A study of Mus musculus with 18 samples.

How the data were processed

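Polyadenylated RNA was sequenced from 18 mouse samples, 8 whole spleens and 10 preparations of macrophages isolated from the spleen. Per the labels, RNA was extracted with a Qiagen RNeasy kit and libraries were made with a NEBNext Ultra II kit from C57BL/6J mice. The deposited table holds raw counts, whole numbers of reads per Ensembl gene with no normalization, made by the authors with FastQC 0.10.1 and HTSeq 0.10.0 on builds named mm10 and GRCm38. The aligner, the annotation release and the strand setting of the counting are not given in the sources used here. The table held 55414 gene identifiers, of which 52081 matched a symbol by identifier in GENCODE M21. The 3333 that did not match carried 0.343% of all counts. All 18 columns matched a sample.

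Libraries were grouped by title into spleen air (n = 4), spleen PM2.5 (n = 4), macrophage air (n = 5) and macrophage PM2.5 (n = 5). The titles of the PM2.5 groups read CAP, which the labels do not expand, and also hold the word Air. CAP was read as PM2.5 from the treatment tags. Macrophage PM2.5 replicate 1 carries an air tag in its treatment field, against its description and the CAP in its title. It was grouped by title, and it was also counted as air and left out as alternatives. The labels do not say that equal replicate numbers pair the animals of the 2 groups, and the comparisons were not paired.

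Total counts per library lay between 16493694 and 20352346 in spleen air, 18427891 and 19906706 in spleen PM2.5, 18107264 and 29013034 in macrophage air, and 18848048 and 33844807 in macrophage PM2.5. Genes with at least 1 count numbered between 19694 and 24641 per library. No library was a copy of another within its group, and libraries of different groups were not compared in this way.

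Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with a minimum count of 10 and a minimum total count of 15. Libraries were scaled with TMM and tested with the quasi-likelihood test on group means, two-sided, and p-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. Each experiment was fitted alone. The difference of the PM2.5 effect between macrophages and spleen was tested as a contrast in a joint fit of all 18 libraries. Log2 fold changes are PM2.5 minus air, with the standard error (SE) of the fit. Levels are CPM, the count of a gene relative to the TMM-scaled library total, as mean ± SD. The levels of cell markers set side by side for the 2 preparations were scaled over all 18 libraries together. Adjusted p-values for genes are from edgeR unless another tool is named.

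Gene lists of cell types, erythroid and macrophage functions, metabolism, proliferation, stress and immune responses were fixed before the data were examined, as were the groups, the tests, the main alternatives and the rule for naming genes. Lists with at least 3 tested members were tested with camera in limma 3.58.1 with a preset inter-gene correlation of 0.01, adjusted over the lists. The same test with an estimated correlation, and the directional test of fry, were alternatives. Adjusted p-values for lists are from camera with the preset correlation unless stated. Within a list, p-values were also adjusted over the list alone.

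Named genes were, per comparison, the called genes with a symbol, a mean of at least 1 CPM and groups that did not overlap, up to 8 per direction by p. To these were added the 3 members with the smallest p of up to 8 called lists, and a fixed set of genes of iron handling, macrophage identity, erythroid regulation and xenobiotic response. For the difference between the experiments, 5 genes per direction with the smallest p were named. List members of other lists past the threshold were allowed as examples. Alb, Fos, Itgad and Pla2g7 were named after their values were seen.

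The alternatives fixed in advance were DESeq2's size factors and upper-quartile scaling in edgeR, DESeq2 1.42.0, limma-voom, no filter, a filter of at least 1 CPM in every library of a group, a robust fit, the joint fit, a replicate block, a threshold of 0.1 and the omission of each library in turn. Chosen after the data were seen were offsets for transcript length and GC content, the omission of both spleen air libraries with liver transcripts, and the omission of spleen PM2.5 replicates 2 and 4. Length and GC content were those of the longest annotated transcript of each gene. They were known for 99.6% of the tested spleen genes and 99.5% of the tested macrophage genes.

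The steps were tested on simulated data with planted changes. In simulated spleen counts, 0 of 67 genes changed 1.5-fold were recovered with edgeR, 38.8% of those changed 2-fold and 84.8% of those changed 4-fold. In simulated macrophage counts these shares were 43.3%, 86.6% and 100%. Of the calls, 4.6% were of unchanged genes in the spleen simulation and 3.49% in the macrophage simulation. In the simulated difference between the experiments, 54% of the genes changed 2-fold were recovered, and 4.42% of the calls were of unchanged genes. Camera called 0 of the 49 and 0 of the 47 unchanged lists. The simulated genes varied independently of one another, so this does not show how camera behaves on correlated lists. In other splits of the real libraries camera called up to 31 spleen and 30 macrophage lists. Figures were drawn with matplotlib. Sequence reads were not analysed here.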

Results

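Gene expression was measured in 2 experiments on mice exposed to filtered air or to PM2.5, fine airborne particles, and the series title names erythrocyte turnover as the subject. In the first experiment whole spleens were taken after 30 days, with 4 libraries per group. In the second, macrophages were isolated from the spleen, with 5 libraries per group. The labels of the second experiment mention filtered air following 30 days of air or PM2.5, and do not say whether this was a recovery period. Libraries held between 16493694 and 20352346 counts in spleen and between 18107264 and 33844807 counts in macrophages.

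The preparations differed in content, as the levels of cell markers in the air groups show. Vcam1, an adhesion molecule of red pulp macrophages, had 6063 ± 763 CPM in macrophage air libraries (SD, n = 5) and 119.5 ± 34.5 CPM in spleen air libraries (SD, n = 4). Slc40a1, which encodes the iron exporter ferroportin, had 3208 ± 688 and 36.3 ± 17.6 CPM. Cd3e of T cells had 6.44 ± 1.18 CPM in macrophage and 91.7 ± 10.7 CPM in spleen air libraries, and Cd79a of B cells 456 ± 88.1 and 1261 ± 282 CPM. Transcripts of other cells were present in the macrophage preparations, some at higher means than in spleen. Hba-a1, an alpha globin, had 2253 ± 1000 CPM in macrophage and 456.5 ± 512 CPM in spleen air libraries. Ighm, the heavy chain of IgM, had 8174 ± 6540 and 3631 ± 1010 CPM. These levels were not tested between the preparations, since material and experiment cannot be separated.

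The first comparison asked how the whole spleen differed after 30 days of PM2.5. Clca3a1, a gene of the calcium-activated chloride channel regulator family (ENSMUSG00000056025, GRCm38 chromosome 3, 144729677 to 144760977, minus strand), rose from 5.72 ± 1.93 to 28.5 ± 4.96 CPM (SD, n = 4 each; log2 fold change 2.32, SE 0.247, adjusted p = 0.0234). Gdpd2, a glycerophosphodiester phosphodiesterase domain gene (ENSMUSG00000019359, chromosome X, 100729873 to 100738895, plus strand), rose from 1.45 ± 0.952 to 17.5 ± 5.35 CPM (log2 fold change 3.60, SE 0.442, adjusted p = 0.0474). Both were higher in all 4 PM2.5 libraries than in any air library. These were the 2 genes past the threshold among 16551 tested. At an unadjusted p under 0.05 there were 2763 genes, 1478 higher and 1285 lower, where no effect would give 828. DESeq2 called 830 genes, 542 higher and 288 lower, and limma-voom called 1. In 8.95% of the tested genes the groups did not overlap, where chance gives 2.86% on average. Genes vary together, so a single chance split can lie far from this value and from the 828. Neither count was compared with other splits of the libraries. The edgeR count was 219 without air replicate 2 and 136 without PM2.5 replicate 1, 1 without air replicate 4, and 0 without air replicate 3 or without PM2.5 replicate 2, 3 or 4. Without air replicate 1, 2 genes were called and Gdpd2 was not among them (adjusted p = 0.0786).

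Erythroid genes rose as lists in spleen. All 19 tested erythroid transcription factor and progenitor genes were higher after PM2.5, with a median log2 fold change of 3.77 (adjusted p = 4.95e-12 for the list). All 21 tested genes of the red cell membrane and of red cell maturation were higher, with a median of 1.80 and a mean of 2.85 (5.12e-11). So were all 17 genes of heme and globin synthesis, with a median of 1.32 (9.05e-09). For each of these 3 lists, the adjusted p was 0.419 with an estimated correlation. Over all genes tested, 0 of their members passed in edgeR, and adjusted over the list alone 17, 17 and 14 did. Epor, the erythropoietin receptor, had 1.34 ± 0.764 CPM in air and 19.3 ± 21.9 CPM in PM2.5 libraries (SD, n = 4 each; adjusted p = 0.118). Klf1, an erythroid transcription factor, had 2.0 ± 1.63 and 31.8 ± 39.4 CPM (adjusted p = 0.14). Sptb, which encodes the beta spectrin of red cells, had 1.51 ± 0.626 and 79.7 ± 110 CPM (adjusted p = 0.0941). Alas2, the erythroid enzyme that starts heme synthesis, had 23.8 ± 28.3 and 268 ± 280 CPM (adjusted p = 0.135). The PM2.5 libraries differed widely, with a mean log2(CPM + 1) of the erythroid factor list of 6.72 in replicate 2, 5.20 in replicate 4, 4.18 in replicate 3 and 2.58 in replicate 1. In air it was 3.20 in replicate 1 and between 2.19 and 2.58 in the others. Without PM2.5 replicate 2 the mean log2 fold changes of the 3 lists fell from 3.22 to 2.12, from 2.85 to 1.80 and from 1.61 to 1.04.

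**Figure D1:**
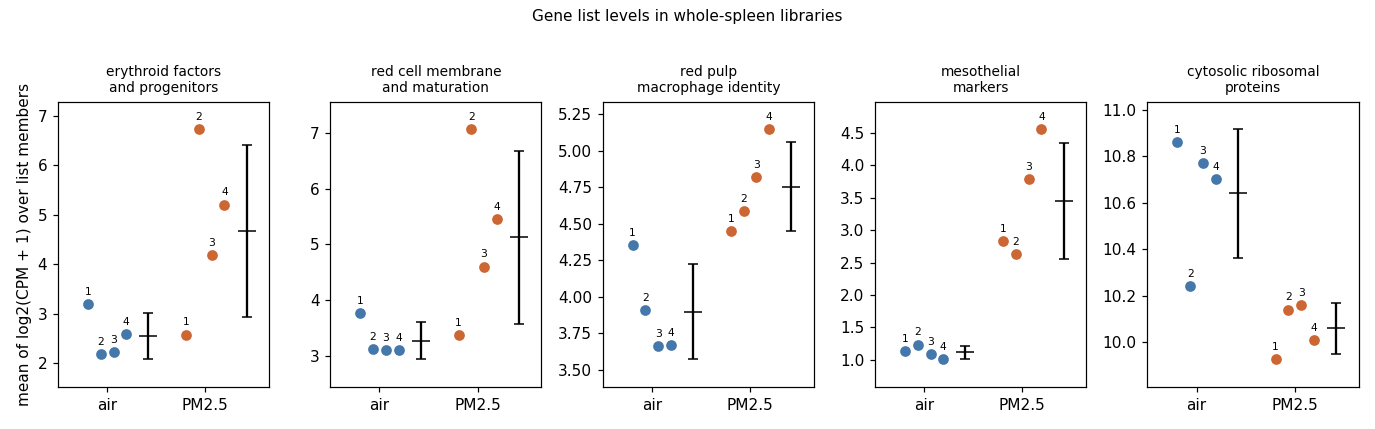
Each panel gives the mean log2(CPM + 1) over the members of a gene list in the 4 air and 4 PM2.5 spleen libraries, with numbered points for replicates and a black bar for mean ± SD. PM2.5 replicate 2 had the highest erythroid factor level at 6.72, and PM2.5 replicate 1, at 2.58, lay below air replicate 1 at 3.20.

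Genes of red pulp macrophages, which take up aged red cells and recycle their iron, rose as a list in spleen. Of 17 tested, 15 were higher and 2 lower, with a median log2 fold change of 0.75 (adjusted p = 2.24e-09, and 0.419 with an estimated correlation). Over all genes tested 0 passed in edgeR, and adjusted over the list alone 11 did. Cd163, the receptor for hemoglobin bound to haptoglobin, had 2.24 ± 0.747 CPM in air and 11.1 ± 6.25 CPM in PM2.5 libraries (SD, n = 4 each; adjusted p = 0.0941). Slc40a1 had 42.0 ± 21.6 and 100.1 ± 25.3 CPM (adjusted p = 0.124). Siglece, an inhibitory lectin receptor, had 1.96 ± 0.551 and 8.98 ± 4.77 CPM (adjusted p = 0.0941). Stab2, a scavenger receptor also known from sinusoidal endothelium, had 12.97 ± 3.19 and 41.5 ± 10.5 CPM (adjusted p = 0.0613). Spic, the transcription factor of red pulp macrophages, had 37.8 ± 13.7 and 45.5 ± 6.45 CPM (adjusted p = 0.581). Hmox1, which degrades heme, had 78.6 ± 53.6 and 132 ± 44.6 CPM (adjusted p = 0.355). Over the alternatives the log2 fold change lay between 0.30 and 1.35 for Hmox1 and between 0.06 and 0.55 for Spic, without a call for either. Vcam1 had 138 ± 43.5 and 198 ± 22.4 CPM (adjusted p = 0.211). The ferritin genes Fth1 and Ftl1 had log2 fold changes of -0.12 (SE 0.163, adjusted p = 0.742) and -0.13 (SE 0.133, adjusted p = 0.657). Timd4, a receptor for dying cells, had a log2 fold change of -0.19 (SE 0.206, adjusted p = 0.674). Genes of heme degradation and iron recycling rose as a list (21 of 30 higher, median 0.24, adjusted p = 0.00209, and 0.419 with an estimated correlation; 5 higher adjusted over the list alone, 0 over all genes tested). Erythrocyte clearance receptors did too (20 of 28 higher, median 0.24, adjusted p = 7.27e-05, and 0.419 with an estimated correlation; 7 higher adjusted over the list alone, 0 over all genes tested). The iron recycling call was lost without PM2.5 replicates 2 and 4, which held the most erythroid transcripts (mean 0.16 instead of 0.49, adjusted p = 0.24). It was also lost without both air libraries with liver transcripts, with a similar mean (0.47, adjusted p = 0.0682).

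Ribosomal protein genes fell as a list. All 53 were lower, with a median log2 fold change of -0.60 (adjusted p = 6.51e-44, and 0.419 with an estimated correlation). Adjusted over the list alone all 53 passed, while over all genes tested 0 did in edgeR. Rpl38 had 1045 ± 315 CPM in air and 513 ± 81.7 CPM in PM2.5 libraries (SD, n = 4 each; adjusted p = 0.114). Rps27 had 2583 ± 777 and 1359 ± 103 CPM (adjusted p = 0.118). Rps28 had 735 ± 200 and 386 ± 67.5 CPM (adjusted p = 0.118). Genes of oxidative phosphorylation fell as a list, with 44 of 47 lower and a median of -0.38 (adjusted p = 5.33e-17, and 0.419 with an estimated correlation). Of its members, 24 were lower adjusted over the list alone and 0 over all genes tested. Its members Atp5e, Cox6b1 and Uqcrq had log2 fold changes of -0.58 (SE 0.144), -0.69 (SE 0.173) and -0.59 (SE 0.148), each with an adjusted p of 0.126. Cholesterol synthesis genes fell (18 of 22 lower, median -0.27, adjusted p = 0.000102, and 0.2 with an estimated correlation; 5 lower adjusted over the list alone, 0 over all genes tested). This was the list that passed in the directional test of fry (adjusted p = 0.0189). Markers of T cells (17 of 19 lower, median -0.31, adjusted p = 2.96e-06) and of B cells (15 of 16 lower, median -0.20, adjusted p = 0.00251) fell, each with an adjusted p of 0.419 with an estimated correlation. Adjusted over the list alone 3 T cell and 2 B cell markers were lower, and over all genes tested 0. The T cell mean moved from -0.32 to -0.21 without air replicate 3. The B cell call was lost without PM2.5 replicate 2 (adjusted p = 0.0813) or without replicates 2 and 4 (0.3).

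Mesothelial, matrix, endothelial and platelet markers rose as lists in the PM2.5 spleens. All 9 tested mesothelial markers were higher, with a median log2 fold change of 4.78 (adjusted p = 3.82e-16, and 0.2 with an estimated correlation). Of these, 8 passed adjusted over the list alone and 0 over all genes tested. Msln, mesothelin, had 1.34 ± 0.943 CPM in air and 32.5 ± 28.7 CPM in PM2.5 libraries (SD, n = 4 each; adjusted p = 0.0845). Upk1b, a uroplakin, had 0.283 ± 0.14 and 9.17 ± 7.84 CPM (adjusted p = 0.0613). Muc16, a mucin, had 8 counts over the air libraries, 3 of them at 0, and 1129 counts over the PM2.5 libraries (adjusted p = 0.0845). Matrix genes rose as a list (26 of 27 higher, median 0.87, adjusted p = 1.65e-09, and 0.419 with an estimated correlation). Without PM2.5 replicate 4 their mean log2 fold change fell from 0.94 to 0.47, and that of Col3a1 from 1.83 to 1.04. Col3a1 had 27.5 ± 9.41 and 97.9 ± 84.2 CPM (adjusted p = 0.133). Col14a1 had 17.8 ± 1.81 and 45.5 ± 24.2 CPM (adjusted p = 0.118) and Col4a1 36.1 ± 6.64 and 62.0 ± 20.8 CPM (adjusted p = 0.14). Endothelial markers (13 of 16 higher, median 0.72, adjusted p = 2.5e-05) and platelet markers (16 of 17 higher, median 0.82, adjusted p = 7.05e-07) rose. Both lists had an adjusted p of 0.419 with an estimated correlation. The matrix, endothelial and platelet lists had 14, 6 and 5 members higher adjusted over the list alone and 0 over all genes tested. Alb, a liver transcript, stood at 30.5 and 55.3 CPM in air replicates 3 and 4 and at no more than 5.97 CPM in the other spleen libraries. Without these 2 air libraries 0 genes were called in edgeR, with log2 fold changes still at 2.065 for Clca3a1 (adjusted p = 0.689) and 3.78 for Gdpd2 (adjusted p = 0.16). The mesothelial level was highest in PM2.5 replicate 4 and lowest among PM2.5 libraries in replicate 2, which had the highest erythroid level. Whether the PM2.5 samples held a larger share of capsule tissue was not tested, so the rise of these lists cannot be assigned to PM2.5.

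Of the other spleen lists past the threshold, neutrophil markers rose (13 of 14 higher, median 1.63, adjusted p = 0.00209, and 0.419 with an estimated correlation). Their mean of 1.82 became 1.13 without PM2.5 replicate 4 and 3.15 without air replicate 1. Lists that rose also included complement and Fc receptor genes (15 of 18 higher, median 0.31, adjusted p = 0.00272) and alternative activation markers (13 of 18 higher, median 0.27, adjusted p = 0.0139). Stromal markers (13 of 18 higher, median 0.59, adjusted p = 0.00268) and glucocorticoid-responsive genes (11 of 14 higher, median 0.33, adjusted p = 0.0104) rose. Both calls were lost without air replicate 2 (adjusted p = 0.0691 and 0.103), with means of 0.65 instead of 0.70 and 0.46 instead of 0.52. The stromal mean fell from 0.70 to 0.46 without PM2.5 replicate 4. Without both air libraries with liver transcripts, the complement and alternative activation calls were lost (0.244 and 0.257), and without PM2.5 replicates 2 and 4 the latter was too (0.0641). Each of these 4 lists had an adjusted p of 0.419 with an estimated correlation. All 36 G2 and mitosis genes were higher (median 0.77, adjusted p = 7.27e-05, and 0.599 with an estimated correlation). The call was lost without PM2.5 replicate 2 (mean 0.11, from 0.78 with all libraries, adjusted p = 0.666), without PM2.5 replicates 2 and 4 (mean -0.042, adjusted p = 0.348) and without both air libraries with liver transcripts (mean 0.57, adjusted p = 0.0682). Antigen presentation genes fell (12 of 15 lower, median -0.19, adjusted p = 0.0151, and 0.499 with an estimated correlation). That call was lost without air replicate 4 (0.107), PM2.5 replicate 2 (0.138) or PM2.5 replicates 2 and 4 (0.566), and with offsets for length and GC content, with a similar mean (-0.17 instead of -0.16, adjusted p = 0.0568). Plasma cell markers rose (13 of 16 higher, median 0.34, adjusted p = 0.0349, and 0.56 with an estimated correlation). The plasma cell call was lost without air replicate 3 (0.386) or 4 (0.0559) or PM2.5 replicate 1 (0.107) or 2 (0.131). In these settings the mean of 0.39 became 0.21, 0.387, 0.369 and 0.34. The call was also lost without both air libraries with liver transcripts (0.942) or without PM2.5 replicates 2 and 4 (0.113). Adjusted over the list alone, 4 neutrophil markers were higher and 1 lower, and 4 alternative activation markers and 4 glucocorticoid-responsive genes were higher. Likewise 6 stromal markers were higher and 1 lower. For the other lists just named 0 members passed in this way, and over all genes tested 0 members of any of these lists passed in edgeR. Of the 49 spleen lists tested, 23 passed with camera, 17 up and 6 down, and 0 passed with an estimated correlation.

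The second comparison asked how macrophages isolated from the spleen differed between PM2.5 and air. All 33 tested genes of S phase and replication were higher after PM2.5, with a median log2 fold change of 0.47 (adjusted p = 1.73e-29, and 0.293 with an estimated correlation). All 36 tested genes of G2 and mitosis were higher, with a median of 0.58 (adjusted p = 1.46e-22, and 0.398 with an estimated correlation). Adjusted over the list alone, 28 of the former and 5 of the latter were higher, and over all genes tested 0 were. Within groups the cell cycle score rose with the erythroid score over the 10 libraries (Pearson r 0.946, exact permutation p = 0.00125), and removing that slope left 0.322 of the difference of 0.57. Mcm6, a subunit of the replicative helicase, had 65.3 ± 10.3 CPM in air and 92.1 ± 4.41 CPM in PM2.5 libraries (SD, n = 5 each; adjusted p = 0.258). Tyms, thymidylate synthase, had 8.26 ± 2.03 and 14.4 ± 1.61 CPM (adjusted p = 0.258). Aurkb, a mitotic kinase, had 15.3 ± 3.77 and 22.9 ± 2.98 CPM (adjusted p = 0.287). In edgeR 0 of 15696 tested genes passed, the smallest adjusted p being 0.183. Of these genes 1704 had an unadjusted p under 0.05, 980 higher and 724 lower, where no effect would give 785 on average. Other splits were not compared on this count either. DESeq2 called 175 genes, 136 higher and 39 lower, and limma-voom called 0. The edgeR count was 17 without air replicate 4 and 3 without PM2.5 replicate 2.

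Markers of several other blood cells rose as lists in the macrophage preparations after PM2.5. Plasma cell markers rose (15 of 16 higher, median 1.01, adjusted p = 3.3e-12, and 0.293 with an estimated correlation). Of these, 7 were higher adjusted over the list alone and 0 over all genes tested. The immunoglobulin heavy chain gene Ighg2c had 53.1 ± 36.9 CPM in air and 242 ± 93.1 CPM in PM2.5 libraries (SD, n = 5 each; adjusted p = 0.281), and Ighg2b 64.3 ± 54.7 and 380 ± 377 CPM (adjusted p = 0.287). Neutrophil markers rose (14 of 16 higher, median 1.51, adjusted p = 1.8e-11, and 0.331 with an estimated correlation). Of these, 10 were higher adjusted over the list alone and 0 over all genes tested. Those with the smallest p were genes of the primary granules of immature neutrophils. Prtn3 had 0.62 ± 0.124 and 3.0 ± 2.05 CPM (adjusted p = 0.258), Mpo 1.26 ± 0.932 and 6.69 ± 3.79 CPM (adjusted p = 0.258) and Elane 0.394 ± 0.289 and 2.97 ± 2.38 CPM (adjusted p = 0.258). Germinal centre B cell markers rose (9 of 10 higher, median 0.74, adjusted p = 7.54e-07, and 0.398 with an estimated correlation; 2 higher adjusted over the list alone, 0 over all genes tested). So did erythroid factor and progenitor genes (18 of 19 higher, median 0.67, adjusted p = 3.36e-06, and 0.56 with an estimated correlation; 2 higher adjusted over the list alone, 0 over all genes tested). Of the latter, Car1 had 13.8 ± 7.51 and 49.3 ± 24.3 CPM and Tfr2 2.09 ± 1.04 and 5.91 ± 2.29 CPM (both adjusted p = 0.287). The mean of this list, 0.68, was 0.44 without air replicate 3 and 1.04 without air replicate 5, and that of the germinal centre list, 0.83, was 1.41 without air replicate 4. Kit had 67.3 ± 23.0 and 49.1 ± 8.90 CPM (adjusted p = 0.472). T cell markers rose (17 of 19 higher, median 0.46, adjusted p = 1.33e-05, and 0.56 with an estimated correlation). So did those of basophils, mast cells and eosinophils (12 of 14 higher, median 0.53, adjusted p = 0.000137, and 0.293 with an estimated correlation). The T cell call was lost with replicate 1 of the PM2.5 group, whose treatment tag says air, counted as air (adjusted p = 0.251). In that setting the plasma cell and neutrophil lists stayed past the threshold, with means of 0.47 instead of 1.08 and 0.54 instead of 1.28.

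**Figure D2:**
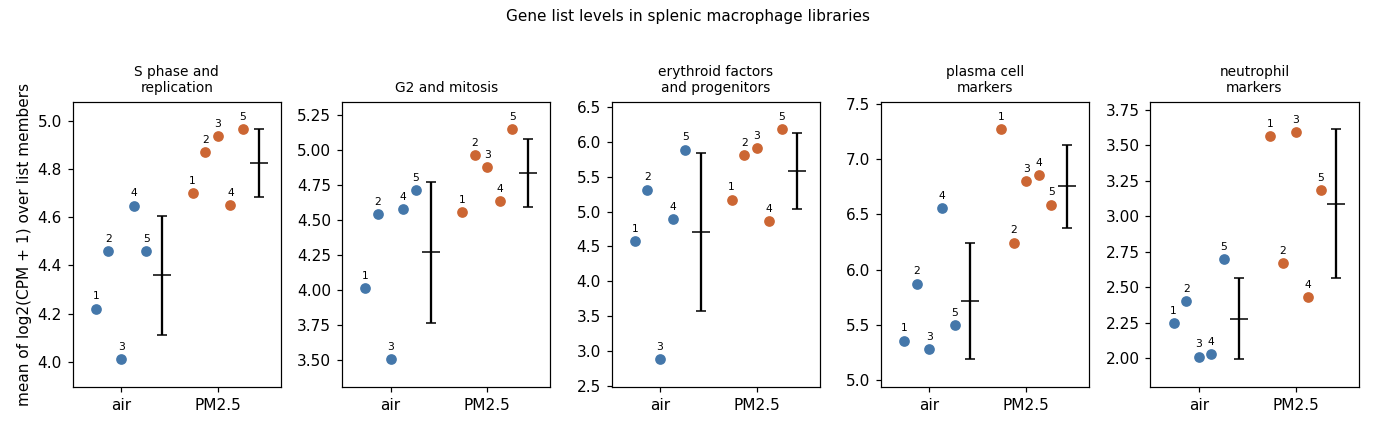
Each panel gives the mean log2(CPM + 1) over the members of a gene list in the 5 air and 5 PM2.5 macrophage libraries, with numbered points for replicates and a black bar for mean ± SD. Air replicate 3 had the lowest erythroid factor level at 2.88, and PM2.5 replicate 5 the highest at 6.18.

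Lists of macrophage and dendritic cell markers fell. Red pulp macrophage genes fell as a list (16 of 17 lower, median -0.22, adjusted p = 0.00044, and 0.619 with an estimated correlation). Over all genes tested or adjusted over the list alone 0 members passed, and the call was lost without PM2.5 replicate 4 (adjusted p = 0.0622). Of its members and the fixed genes, Cd163 had 880 ± 128 CPM in air and 727 ± 28.5 CPM in PM2.5 libraries (SD, n = 5 each; adjusted p = 0.374), Stab2 387 ± 55.6 and 296 ± 34.5 CPM (adjusted p = 0.298) and Vcam1 5460 ± 692 and 5212 ± 619 CPM (adjusted p = 0.861). Slc40a1 had 2892 ± 639 and 2892 ± 499 CPM (adjusted p = 0.999), Hmox1 2467 ± 428 and 2778 ± 597 CPM (adjusted p = 0.735) and Spic 577 ± 60.7 and 538 ± 90.9 CPM (adjusted p = 0.791). Alas2 had 238 ± 114 and 238 ± 64.3 CPM (adjusted p = 0.999), and Fth1 2482 ± 237 and 2505 ± 438 CPM (adjusted p = 0.979). Conventional dendritic cell markers fell (14 of 16 lower, median -0.38, adjusted p = 1.06e-06, and 0.398 with an estimated correlation). Flt3 had 75.8 ± 26.7 and 50.6 ± 9.06 CPM (adjusted p = 0.368) and Itgax 298 ± 73.5 and 223 ± 25.1 CPM (adjusted p = 0.383). Immediate early genes, which cells induce within minutes of stimulation, fell (23 of 24 lower, median -0.23, adjusted p = 1.53e-07, and 0.293 with an estimated correlation). Egr1 had 473 ± 88.9 and 359 ± 25.7 CPM (adjusted p = 0.312) and Klf4 171 ± 20.2 and 125 ± 22.5 CPM (adjusted p = 0.287). Socs3, the member with the smallest p, was the exception with 30.8 ± 2.85 and 39.7 ± 4.04 CPM (adjusted p = 0.258, and 1 higher adjusted over the list alone). Fos, another immediate early gene, had 1757 ± 127 CPM in macrophage air and 3.15 ± 0.878 CPM in spleen air libraries, with all 18 libraries scaled together. Whether the isolation of the cells set such levels was not tested.

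Further macrophage lists passed with smaller changes. Unfolded protein response genes rose (19 of 20 higher, median 0.27, adjusted p = 4.59e-06, and 0.543 with an estimated correlation). That call was lost with the library of the conflicting label counted as air (0.251). Ribosomal protein genes (53 of 53 higher, median 0.18, adjusted p = 2.47e-05) and oxidative phosphorylation genes (47 of 47 higher, median 0.15, adjusted p = 6.34e-05) rose, each with an adjusted p of 0.744 with an estimated correlation. Both calls were lost without PM2.5 replicate 1 (adjusted p = 0.841 and 0.815) and with offsets for length and GC content (0.405 and 0.644). With that library counted as air, both lists were lower, with mean log2 fold changes of -0.14 and -0.11. Heme and globin synthesis (17 of 17 higher, median 0.19, adjusted p = 0.00755) and red cell membrane genes (20 of 23 higher, median 0.36, adjusted p = 0.0125) rose, each with an adjusted p of 0.744 with an estimated correlation. Both calls were lost without air replicate 1 (0.131 and 0.119), air replicate 3 (0.186 and 0.407) or PM2.5 replicate 5 (0.11 and 0.189), and the second also without PM2.5 replicate 3 (0.0509). Without air replicate 5 their means rose from 0.24 to 0.42 and from 0.32 to 0.67. Monocyte markers (10 of 14 higher, median 0.23, adjusted p = 0.00519, and 0.543 with an estimated correlation) rose, a call lost without air replicate 2 (0.0679) or 4 (0.0573), with a mean of 0.17 instead of 0.26 without PM2.5 replicate 1. Glycolysis genes (17 of 19 higher, median 0.11, adjusted p = 0.0201, and 0.543 with an estimated correlation) rose, a call lost without air replicate 2 (0.0679) or PM2.5 replicate 1 (0.238). Among lists that fell were targets of LXR in cholesterol efflux (13 of 17 lower, median -0.15, adjusted p = 0.0125, and 0.543 with an estimated correlation) and marginal zone macrophage markers (7 of 7 lower, median -0.25, adjusted p = 0.0204, and 0.56 with an estimated correlation). Endothelial markers (11 of 13 lower, median -0.21, adjusted p = 0.0204, and 0.597 with an estimated correlation) fell, as did lysosome genes (29 of 38 lower, median -0.06, adjusted p = 0.0226, and 0.744 with an estimated correlation). The LXR targets lost their call without air replicate 5 (0.0528) or PM2.5 replicate 4 (0.052), and marginal zone markers without air replicate 2 (0.143) or 3 (0.074) or PM2.5 replicate 4 (0.106). Endothelial markers lost it without air replicate 2 (0.136) or PM2.5 replicate 3 (0.0651), 4 (0.103) or 5 (0.11), and their mean of -0.07 was -0.25 without PM2.5 replicate 1. Lysosome genes lost it without air replicate 2 (0.136), 3 (0.0712) or 5 (0.24) or PM2.5 replicate 2 (0.0516), 4 (0.63) or 5 (0.117). Matrix genes rose (12 of 20 higher, median 0.14, adjusted p = 0.0473, and 0.619 with an estimated correlation). They lost the call without air replicate 1 (0.187) or 4 (0.196) or PM2.5 replicate 2 (0.576) or 3 (0.0651). With the library of the conflicting label counted as air, calls were also lost for monocyte (0.42), glycolysis (0.732), LXR target (0.0834), marginal zone (0.0904) and matrix (0.128) lists. Over all genes tested 0 members of any macrophage list passed in edgeR. Adjusted over the list alone, 2 markers of basophils, mast cells and eosinophils, 2 monocyte markers, 2 glycolysis genes, 1 endothelial marker and 1 matrix gene were higher, and 2 endothelial markers were lower. In this way 0 members of the T cell, dendritic cell, unfolded protein response, ribosomal protein, oxidative phosphorylation, heme and globin, red cell membrane, LXR target, marginal zone and lysosome lists passed. Of the 47 macrophage lists tested, 23 passed with camera, 16 up and 7 down, and 0 passed with an estimated correlation or in the directional test of fry. In its mixed test, which ignores direction and was not used for calls, some lists passed, among them S phase genes (0.0208) and plasma cell markers (0.0343).

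The third comparison asked for which genes the PM2.5 effect differed between macrophages and spleen. Ribosomal protein genes and red pulp macrophage genes moved apart. The difference, macrophages minus spleen, was positive for 53 of 53 ribosomal protein genes (median 0.77, adjusted p = 5.98e-36, and 0.451 with an estimated correlation). It was negative for 16 of 17 red pulp macrophage genes (median -0.93, adjusted p = 1.58e-11, and 0.451 with an estimated correlation). Also negative were those of all 19 erythroid factor and progenitor genes (median -2.81, adjusted p = 7.97e-05, and 0.49 with an estimated correlation). Of these lists, 4 ribosomal protein genes, 4 red pulp macrophage genes and 1 erythroid gene passed over all genes tested, and 53, 12 and 10 adjusted over the list alone. Stab2 had the second smallest p of all genes, with a difference of -2.08 (SE 0.253, adjusted p = 0.00106), from 1.68 in spleen and -0.39 in macrophages when each experiment was fitted alone. Hcar2, a hydroxycarboxylic acid receptor, had a difference of -3.0 (SE 0.442, adjusted p = 0.00654), and Gdpd2 of -3.85 (SE 0.536, adjusted p = 0.00495). Ly6c2, a surface protein of monocytes with the close paralog Ly6c1, had 96.6 ± 28.2 CPM in air and 71.2 ± 6.07 CPM in PM2.5 spleens (SD, n = 4 each) and 19.5 ± 3.05 and 34.0 ± 4.39 CPM in macrophages (SD, n = 5 each). Its difference was 1.24 (SE 0.229, adjusted p = 0.0183). Yeats4, a reader of acetylated histones, had a difference of 0.72 (SE 0.144, adjusted p = 0.0212), and Mlc1 of 2.90 (SE 0.523, adjusted p = 0.0183). Syt1, a synaptotagmin, had a difference of 3.10 (SE 0.582, adjusted p = 0.0183) and Pcdh15, a protocadherin, of 2.02 (SE 0.403, adjusted p = 0.0212). Mlc1 and Syt1 were near the floor in macrophages. Over the air and PM2.5 macrophage libraries Mlc1 had 15 and 71 counts and Syt1 17 and 102. Over the air and PM2.5 spleen libraries Mlc1 had 533 and 360 counts and Syt1 722 and 536.

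The smallest p was that of 4931431B13Rik, a processed transcript annotated on the strand opposite to Itgad, which had 4 counts over the spleen air libraries, 3 of them at 0, and 180 over the spleen PM2.5 libraries. In macrophages it had 9705 counts in air and 10016 in PM2.5. The antisense transcript 1700071M16Rik, opposite to Pla2g7, had 3 counts in spleen air, 69 in spleen PM2.5, 1434 in macrophage air and 1396 in macrophage PM2.5 libraries. Their fitted differences of -5.35 (adjusted p = 5.81e-05) and -4.44 (adjusted p = 0.00654) depend on the prior count of the fit. Over the alternatives they lay between -8.71 and -4.92 and between -7.44 and -4.03. In all, 259 of 17779 genes passed, 74 with a positive and 185 with a negative difference, and 3662 had an unadjusted p under 0.05. DESeq2 called 1044 and limma-voom 3. The balance of directions depended on the scaling, with 38 positive of 230 called with DESeq2's size factors, and on the offsets for length and GC content, with 193 positive of 378 called. Without 1 spleen library the count was 1317 (air replicate 2), 68 (air 3), 96 (air 4), 130 (PM2.5 3) or 79 (PM2.5 4). Without 1 macrophage library it was 105, 91, 78, 164 and 72 for air replicates 1 to 5, and 152, 128, 75 and 127 for PM2.5 replicates 1, 3, 4 and 5. Without 1 library, Yeats4 was no longer past the threshold for spleen air replicate 3 or 4, spleen PM2.5 replicate 4, macrophage air replicate 5 or macrophage PM2.5 replicate 4 (highest adjusted p = 0.0572). Pcdh15 was not for spleen air replicate 3 or macrophage air replicate 3 or 5 (highest adjusted p = 0.0514).

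Across the 14696 genes tested in both experiments, log2 fold changes of macrophages and spleen had a Pearson r of 0.0758 and a Spearman rho of -0.173 across genes, which are not independent replicates. Of these genes 40.9% had the same sign. Of the 34 lists past the threshold in either experiment, 12 passed in both, and 5 of these in opposite directions. Those 5 were ribosomal protein genes, oxidative phosphorylation and T cell markers, each lower in spleen and higher in macrophages, and red pulp macrophage genes and endothelial markers, each higher in spleen and lower in macrophages. For each of the 5, the difference itself passed with camera and did not pass with an estimated correlation (adjusted p between 0.451 and 0.49). The ribosomal and oxidative phosphorylation calls in macrophages rested on PM2.5 replicate 1, without which they were lost (0.841 and 0.815). With it counted as air both lists were lower in macrophages, as in spleen, and the T cell call was lost (0.251). The macrophage red pulp call was lost without PM2.5 replicate 4 (0.0622). The macrophage endothelial call was lost without any 1 of 4 libraries (0.0651 to 0.136, mean 0.014 without air replicate 2) and with offsets for length and GC content (0.133).

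**Figure D3:**
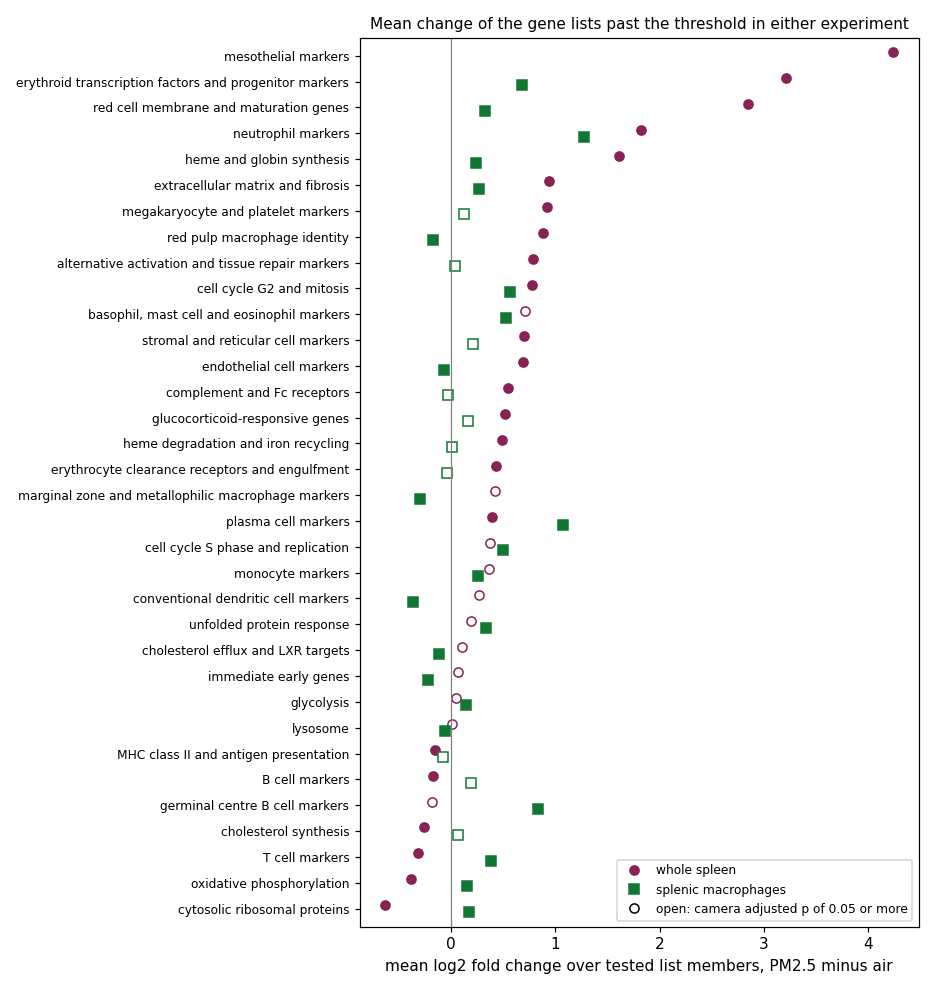
Mean log2 fold change, PM2.5 minus air, of the 34 gene lists past the threshold in either experiment, for spleen and for macrophages, with filled points for an adjusted p under 0.05 with camera and open points for the others. Ribosomal protein genes had means of -0.63 in spleen and 0.17 in macrophages, and mesothelial markers had the largest mean in spleen at 4.24.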

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

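Chosen after the results were seen were the tests on B and T cell share, on PM2.5 replicate 2, on blood left in the spleen and on carry-over of erythroid cells, and the removal of the erythroid slope from the cell cycle score. The test on blood replaced a test on capsule tissue whose outcome hung on 1 library, and both outcomes could be foreseen from the library values. Among 248 pairs of a group and a result, 15 had a library apart from the others of its group, 6.05%, where chance gives about 1 in 20. Of these, 5 lay in spleen air replicate 1, the highest of its group for Slc4a1 (log2 CPM 4.57), Hmox1 (7.31), Vcam1 (7.66), the red cell membrane list (mean log2 CPM 4.13) and the neutrophil list (2.19). Spleen PM2.5 replicate 1 was the lowest of its group for Cox6b1 (6.45) and Uqcrq (5.90). Muc16 stood at -0.90 in spleen air replicate 2, the air library in which it had counts. Macrophage air replicate 3 was the lowest for Car1 (1.06) and Tfr2 (-1.12). Macrophage PM2.5 replicate 4 was the lowest for Hmox1 (10.8) and Stab2 (7.88). Macrophage PM2.5 replicate 1, the library with the conflicting label, was the highest for the oxidative phosphorylation list (6.49). Macrophage air replicate 5 was the lowest for the T cell list (2.47), and macrophage air replicate 2 for the glycolysis list (5.85).

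The PM2.5 effect differed between the experiments, as macrophages minus spleen in the joint fit, for 18 named genes and 23 lists, with means over the list members given for the lists. Material, experiment and exposure wording differ together, so these differences cannot be assigned to the cell type. Negative differences were -5.35 for 4931431B13Rik, -4.44 for 1700071M16Rik, -3.85 for Gdpd2, -3.74 for Epor, -3.00 for Hcar2, -2.59 for Cd163, -2.48 for Siglece, -2.08 for Stab2, -1.86 for Clca3a1 and -1.77 for Col14a1. Positive differences were 3.10 for Syt1, 2.90 for Mlc1, 2.02 for Pcdh15, 1.24 for Ly6c2, 1.19 for Rps28, 1.06 for Rps27, 0.885 for Cox6b1 and 0.722 for Yeats4. Among the lists, differences were -3.46 for mesothelial markers, -2.78 for red cell membrane genes, -2.54 for erythroid factors and progenitors, -1.37 for heme and globin synthesis and -1.07 for red pulp macrophage identity. They were -0.797 for endothelial, -0.784 for platelet, -0.734 for marginal zone macrophage and -0.642 for conventional dendritic cell markers. Complement and Fc receptor genes stood at -0.76, alternative activation markers at -0.75, matrix genes at -0.692, clearance receptors at -0.494, iron recycling genes at -0.448 and immediate early genes at -0.298. Mesothelial markers were near the floor in macrophages, so their difference rests on the spleen values. Over the air and PM2.5 macrophage libraries Msln had 11 and 36 counts and Upk1b 1 and 5. Of the matrix genes, Col3a1 was low there too, at 0.85 ± 0.338 CPM in air and 0.73 ± 0.295 CPM in PM2.5 libraries (SD, n = 5 each, all 18 libraries scaled together). Positive list differences were 1.02 for germinal centre B cells, 0.796 for ribosomal proteins, 0.70 for T cells, 0.678 for plasma cells, 0.53 for oxidative phosphorylation, 0.358 for B cells, 0.314 for cholesterol synthesis and 0.129 for S phase. With an estimated correlation 0 of the 23 lists passed. In the directional test of fry those past the threshold were cholesterol synthesis (adjusted p = 0.026), red pulp macrophage identity (0.0405), endothelial markers (0.0431), clearance receptors (0.0431), ribosomal proteins (0.0456) and mesothelial markers (0.048).

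The lower ribosomal protein genes in PM2.5 spleens were weighed first. With offsets for transcript length and GC content the median log2 fold change was -0.558 (SD 0.194 over 53 genes), from -0.597 before (SD 0.138). All 53 genes stayed below 0. This argues against a trend between libraries on length and GC content of the longest annotated transcript as the whole cause. That transcript need not be the one expressed, so a trend on the expressed transcripts stays open. A lower share of B and T cells may contribute. The ribosomal score fell by 0.613 and the B and T cell score by 0.252, and their difference of -0.361 had an exact permutation p of 0.114 (two-sided, 70 arrangements of 4 against 4), so this source cannot be told apart from a change within cells. An effect of PM2.5 on ribosomal transcripts stays open and was not tested further.

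For the higher erythroid genes in PM2.5 spleens, PM2.5 replicate 2 as the whole cause is argued against, since without it the median log2 fold change over 57 genes was 1.87, from 2.27, with 54 of 57 above 0, and without replicates 2 and 4 it was 0.917. With offsets for length and GC content the median was 2.22, which argues against a trend on those of the longest annotated transcripts. More blood left in the PM2.5 spleens and more erythroblasts both stay open. The erythroid factor score and that of globin genes and Alas2 rose by 2.58 and 2.92 (difference -0.34, exact permutation p = 0.429, two-sided, 4 against 4), which decides between them in neither direction. The factor score by itself had an exact permutation p of 0.0571.

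For the higher cell cycle, plasma cell and neutrophil genes in PM2.5 macrophages, 1 possible source was the library with the conflicting label. Without it 4 of the 4 lists stayed past the threshold with camera and higher (with an estimated correlation 0 of the 4 passed with all libraries). This count decides little, since camera called up to 30 macrophage lists in other splits. The median log2 fold changes without it were 0.48 for S phase, 0.65 for G2 and mitosis, 0.90 for plasma cell and 1.28 for neutrophil genes. With all libraries they were 0.47, 0.58, 1.01 and 1.51. These medians argue against that library as the sole cause. With it counted as air the means fell from 1.08 to 0.47 for plasma cell and from 1.28 to 0.54 for neutrophil markers. The trend on length and GC content of the longest annotated transcripts is argued against too, since the median over 101 genes was 0.551 with offsets and 0.586 before. Carry-over of dividing erythroid cells may account for part of the cell cycle genes: after removal of group means, the cell cycle score rose with the erythroid score over 10 libraries (Pearson r 0.946, exact permutation p = 0.00125, Spearman rho 0.854, exact permutation p = 0.00764, and r 0.823 with p = 0.0486 by the same exact permutation without the 2 libraries farthest from the median). The difference of 0.57 in the cell cycle score had an exact permutation p of 0.00794, the smallest that 252 arrangements of 5 against 5 give in a two-sided test. Removing the erythroid slope left 0.322 of it, with the same permutation p. The slope was fitted within the real groups and held fixed over the arrangements, so the p of the remainder is not exact and decides nothing. The erythroid score itself differed by 0.637 (exact permutation p = 0.238). Division of other cells, an effect of PM2.5 and carry-over of other cells stay open.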

How the results depend on the processing

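Omission of PM2.5 replicates 2 and 4, omission of the air libraries with liver transcripts and the offsets for length and GC content were chosen after the data were seen. In spleen, the 2 called genes became 1 with DESeq2's size factors, 1 with limma-voom, 12 with the stricter filter, 62 at a threshold of 0.1, 461 without a filter, 830 with DESeq2 and 1050 in the joint fit, 0 without the air libraries with liver transcripts and 0 without PM2.5 replicates 2 and 4. Without 1 library it lay between 0 and 219. Clca3a1 and Gdpd2 stayed higher in every setting run. Their groups did not overlap, so the omission of libraries could hardly have changed this direction. The adjusted p for Clca3a1 was 0.129 without air replicate 3, 0.0742 without air replicate 4, and 0.0693, 0.0843 and 0.101 without PM2.5 replicates 2, 3 and 4. For Gdpd2 it was 0.0786 and 0.129 without air replicates 1 and 3, and 0.0693, 0.177 and 0.101 without PM2.5 replicates 2, 3 and 4. It was 0.0514 with DESeq2's size factors and 0.105 with limma-voom. Without the air libraries with liver transcripts the log2 fold changes were 2.065 for Clca3a1 (adjusted p = 0.689) and 3.78 for Gdpd2 (0.16). Without PM2.5 replicates 2 and 4 they were 2.115 and 3.45 (both 0.187), against 2.32 and 3.60 with all libraries. In macrophages, the count of 0 became 175 with DESeq2 and 1 without a filter, and lay between 0 and 17 without 1 library. For the difference between the experiments, 259 became 1044 with DESeq2, 3 with limma-voom, 91 with a replicate block and 1102 at a threshold of 0.1, and lay between 68 and 1317 without 1 library. A threshold of 0.1 admits more genes by construction. For the other settings the cause was not tested. The 23 spleen lists became 0 with an estimated correlation and 1 in the directional test of fry, and the 23 macrophage lists 0 and 0. The spleen lists lay between 21 and 27 and the macrophage lists between 19 and 25 without 1 library.

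After removal of group means, the correlations of libraries with the same replicate number lay between -0.137 and 0.0589 in spleen and between -0.143 and 0.284 in macrophages. In macrophages replicates 4 (0.284) and 5 (0.254) had the highest of the 25 correlations, and the other 3 same-number pairs lay below 0. Not every library correlated best with its own number, so the numbers were not taken to pair the samples. With a replicate block 3 genes were called in spleen and 0 in macrophages. With it the adjusted p was 0.0989 for Clca3a1 in spleen, 0.0528 for the difference of Yeats4 and 0.055 for the matrix list in macrophages.

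Some values changed sign, and the cause was not tested. For Alas2 in macrophages, the log2 fold change of 0.0020 became -0.0032 with DESeq2's size factors, -0.0046 with upper-quartile scaling, -0.0042 with DESeq2, -0.0086 with the stricter filter, -0.00076 in the joint fit and -0.021 with offsets for length and GC content, and lay between -0.19 and 0.19 without 1 library. For Slc40a1, -0.00022 became 0.00087 without a filter, 0.0073 with a replicate block and 0.039 with the library of the conflicting label counted as air, and lay between -0.093 and 0.10 without 1 library. For Fth1, 0.013 became -0.058 with the offsets and -0.16 with that library counted as air, and lay between -0.0997 and 0.076 without 1 library. For Ftl1, 0.12 became -0.00045 with the offsets and -0.025 with that library counted as air. With that library counted as air, the mean log2 fold changes of the macrophage lists became -0.11 for oxidative phosphorylation (adjusted p = 0.0029) and -0.14 for ribosomal proteins (adjusted p = 0.000207), both lower and past the threshold. Without 1 library the ribosomal mean lay between -0.0041 and 0.24. The mean of the G2 and mitosis list in spleen, 0.78, became -0.042 without PM2.5 replicates 2 and 4. Of the other values for spleen lists, 278 kept their direction and side of the threshold and 66 lost the threshold. For macrophage lists these were 276 and 89. The direction of a list was that of the camera test and not the sign of its mean. Among the 89, the lysosome mean of -0.060 became 0.0077 without PM2.5 replicate 4. The endothelial mean of -0.070 became 0.014 without air replicate 2, and the oxidative phosphorylation mean of 0.15 became -3.2e-05 with the offsets. For named genes in spleen, 654 values kept both, 105 gained the threshold and 17 lost it. In macrophages 819 kept both and 12 gained the threshold, and for the difference 264 kept both and 16 lost it. With DESeq2's size factors the median log2 fold change of all genes was 0.03 in spleen, 0.0017 in macrophages and -0.063 for the difference. In simulated spleen counts of 4 against 4 libraries, 0 of 67 planted 1.5-fold changes were recovered with edgeR, so the main fit can miss changes of that size there. The other settings were not simulated.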

Other observations

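The values of Itgad and the overlaps with neighbouring genes were examined after the results were seen. Responses often examined after inhaled particles did not pass as lists with camera in either experiment. For NRF2 target genes, which answer oxidative stress, 13 of 23 were higher in spleen (median log2 fold change 0.03, adjusted p = 0.302) and 16 of 23 in macrophages (median 0.09, adjusted p = 0.15). For targets of the aryl hydrocarbon receptor, a sensor of aromatic pollutants, 7 of 9 were higher in spleen (median 0.20, adjusted p = 0.136) and 5 of 9 in macrophages (median 0.13, adjusted p = 0.724). Cyp1b1 had 61.7 ± 10.4 CPM in air and 70.0 ± 4.92 CPM in PM2.5 spleens (SD, n = 4 each; adjusted p = 0.541), and 0.997 ± 0.294 and 1.75 ± 0.53 CPM in macrophages (SD, n = 5 each; adjusted p = 0.36). Nqo1 had 1.14 ± 0.75 and 3.21 ± 2.16 CPM in spleen (adjusted p = 0.251). Inflammatory cytokines and chemokines had medians of -0.13 in spleen (adjusted p = 0.273) and -0.09 in macrophages (adjusted p = 0.0927). Interferon-stimulated genes had a median of -0.07 and a mean of 0.06 in spleen, opposite in sign, with a downward test (adjusted p = 0.379), and an adjusted p of 0.93 in macrophages. Hypoxia response genes (adjusted p = 0.299 and 0.996), p53 target genes (0.834 and 0.119) and heat shock genes (0.961 and 0.422) did not pass with camera in spleen or macrophages. In the mixed test of fry, which ignores direction and was not used for calls, some of these lists passed. In spleen these were the cytokine and chemokine (adjusted p = 0.0198), hypoxia (0.0247) and NRF2 target (0.032) lists. In macrophages they were the targets of the aryl hydrocarbon receptor (0.00494) and of p53 (0.0352).

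Itgad, an integrin subunit of red pulp macrophages on the strand opposite to 4931431B13Rik, had 3.49 ± 3.76 CPM in air and 16.9 ± 10.4 CPM in PM2.5 spleens (SD, n = 4 each; adjusted p = 0.154), and 1704 ± 260 and 1426 ± 191 CPM in macrophages (SD, n = 5 each; adjusted p = 0.491). Since the strand setting of the counting is not given in the sources used here, whether the counts of the antisense transcript came from its own strand was not tested. The same holds for other named genes that overlap a neighbour on the other strand, such as Rps28 with Kank3, Sptb with Plekhg3 and Alas2 with Apex2. Tfrc, the transferrin receptor, had 88.7 ± 20.8 and 212 ± 189 CPM in spleen (adjusted p = 0.225) and 127 ± 58.3 and 163 ± 67.8 CPM in macrophages (adjusted p = 0.705).

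Whether chance splits of the libraries give results as large was counted for each comparison. In spleen, 2 of the 35 splits of the 8 libraries into 4 and 4 gave at least the 2 genes of the real split, and 1 other gave 9. For the number of spleen lists, 7 of 35 splits gave at least the real 23, and the highest other gave 31. In macrophages the real count of genes was 0, so all 100 splits drawn gave at least as many, the highest 6, and this count decides nothing. For macrophage lists, 18 of 100 gave at least the real 23, and the highest other gave 30. For the difference between the experiments, 1 of 100 relabellings, the real one, gave 259 genes, and the highest other gave 106. By this count, no other relabelling drawn reached the real count for the difference. Chance is not excluded for the spleen genes or the lists of either experiment. Only 100 relabellings were drawn. Without 1 library the real count for the difference fell as low as 68, and such fits were not compared with relabellings. An earlier count with fewer relabellings, extended because more could be run, also put the real labels highest, with a lower highest other count.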
